A study of Mus musculus with 16 samples.

How the data were processed

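Genomic DNA of mouse embryonic stem (ES) cells was sequenced after bisulfite treatment, which turns unmethylated cytosine into uracil and leaves methylated cytosine as it is. The 7 bisulfite libraries came from triple-knockout (TKO) cells, which lack the DNA methyltransferases Dnmt1, Dnmt3a and Dnmt3b. Per the labels, 2 of them were denatured with alkali (Alkaline 2 and Alkaline 3) and 3 with heat (Heat 1, Heat 2 and Heat 3). The other 2, meTKO 1 and meTKO 2, are labelled as DNA methylated in vitro with M.CviPI, an enzyme that methylates cytosine after guanine (GpC). The labels do not state the denaturation used for these 2, so they were compared with each protocol separately. A further 9 libraries were inputs, unconverted DNA sequenced as a control: 8 from ES cell lines of different genotypes and 1 from primary embryonic fibroblasts.

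For the bisulfite libraries the deposited files give counts of methylated and unmethylated calls at each CpG cytosine, on both strands, with the same level as a percent. The deposited percent differed from the percent recomputed from the counts only in the last digits a computer stores. The deposited input table gives counts of reads in tiles of 1 kb, not normalized. Per the labels, the authors used Trim Galore 0.2.5, Bismark 0.13.1, Bowtie2 and the mouse build NCBIM37; read filters, removal of duplicate reads and the step that counted reads in tiles are not given in the sources used here. All coordinates are on NCBIM37. The gene table at hand is on another build, so no gene was placed, and the planned tests around gene starts were not run. Per the labels, bisulfite kits of 3 makers were used, without saying which library had which kit. Bisulfite libraries and inputs also differed, per the labels, in adaptors, polymerase and number of PCR cycles, so a comparison between them holds these differences too.

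The percent of methylated calls of a library was computed from pooled calls. In TKO cells without added methylation it counts cytosines that were not converted, apart from sequencing errors. Intervals for single libraries are 95% Wilson intervals. They cover counting error only, since reads carry no molecular identifiers. They also take calls as independent, so they are too narrow where calls share a read. Sequence context was read from positions alone: in CGCG the inner cytosines of both strands follow a guanine and are GpC sites, while the base before the outer cytosines and before a lone CpG is unknown. Tiles of 1 kb were grouped by the number of CpGs seen in any bisulfite library, from 1 to 5, 6 to 10, 11 to 20, 21 to 40, 41 to 60 and over 60. Relative coverage was the number of calls per CpG position (positions seen in any bisulfite library), or reads per tile for inputs, divided by the mean over 2299021 autosomal tiles, on the log2 scale. Repeat-like tiles were the 592 tiles in which the mean of the 8 ES cell inputs exceeded 10 times the autosomal median of 8.13 reads. The input table has no row for 287 tiles that hold bisulfite calls, 15 of them mitochondrial. These tiles were noticed only in the data, were treated as a class of their own, and were left out in alternatives added after the data had been seen. Evenness was the coefficient of variation of relative coverage over autosomal 100 kb windows.

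Single values per library were compared with a two-sided exact permutation test of the difference in means, by full enumeration (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), with Benjamini-Hochberg adjustment within each family (statsmodels 0.14.6). The smallest p these designs allow is 0.2 for 3 against 2 libraries, 0.333 for 2 against 2, 0.0952 for 2 against 5, 0.0121 for 3 against 8 and 0.0444 for 2 against 8. Calls per 100 kb window were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3; TMM, filterByExpr, 1 fit over the 7 bisulfite libraries), and methylated against unmethylated calls with edgeR's model for methylation counts in windows with at least 100 calls in every library. The threshold was an adjusted p of 0.05. Figures were drawn with matplotlib 3.10.9.

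The window tests were tested on simulated data with 100 changed windows of each size. At a 1.5-fold change in calls, 85, 86 and 78% were found for Heat against Alkaline, meTKO against Heat and meTKO against Alkaline, and at a 2-fold change 100, 100 and 97%. Unchanged windows called at either size numbered 9, 10 and 5, so windows called in the data can be false. In these simulations of coverage all libraries shared 1 common profile along the genome. In the data the log2 change went with the number of CpGs per window (Spearman correlation −0.28, 0.74 and 0.65). The shares found and the false calls therefore do not tell how the tests of coverage perform in the data. For levels of Heat against Alkaline, 37% were found at a 4-fold change in odds and 100% at a 16-fold change; these sizes were chosen after smaller ones were seldom found. For levels of meTKO, 18% were found at a 2-fold and 99% at a 4-fold change in odds. False calls of level numbered 3 for Heat against Alkaline and 1 for meTKO. In these simulations of level all libraries shared 1 common level, while the real Heat libraries ranged from 0.312 to 3.54%. The shares found therefore do not tell what the tests of level can find in the data.

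The labels do not say whether replicates came from separate cultures, so every p measures only the spread between these libraries, which may be technical. No 2 libraries of a group agreed within the noise of independent counts: over 1 Mb windows the chi-square per degree of freedom was lowest, 6.95, between Alkaline 2 and Alkaline 3. For bisulfite libraries calls on the same read are not independent, which raises this value by itself. Replicate numbers were checked for pairing across groups. After removal of group means the window profiles of Alkaline 2 and Heat 2 correlated at 0.126 and those of Alkaline 3 and Heat 3 at 0.0563. Those of Heat 1 and meTKO 1 and of Heat 2 and meTKO 2 correlated at −0.304. Deviations within a group of 2 libraries mirror each other, so this check was weak. The numbers were not used to pair samples, except as a block in alternatives.

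The tests, the alternatives and the rule for named regions were fixed before the data were examined, apart from those said to be added. Named regions were the chromosome classes, the density groups and the repeat-like tiles; for each window test, the 5 windows with the largest rise and the 5 with the largest fall among those that passed, with no overlap between the libraries compared and an input between 0.5 and 2 times the median; and each chromosome of an input 0.3 or more (log2) from the median over inputs. Alternatives changed the normalization, tool, filter, window size, call minimum, weighting, denominator, tile class or control set, added the replicate number as a block, or left out each library in turn. Of the autosomes, coverage of chromosome 8 alone was carried through these alternatives, since the others are given only as ranges; this was decided after the values were seen.

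Total calls per bisulfite library ranged from 16736267 to 35394999, with a median of 1 call per covered position, so levels at single CpGs were not compared; pooled classes hold far more calls. Inputs held 8560355 to 79873148 reads. All libraries were used.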

Results

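Whole-genome bisulfite sequencing of TKO ES cells, which lack the 3 DNA methyltransferases, was compared between alkaline (2 libraries) and heat denaturation (3 libraries), with 2 libraries labelled as DNA methylated in vitro (meTKO) and 9 unconverted inputs. Total calls were 35394999 in Alkaline 2, 17676186 in Alkaline 3, 19501628 in Heat 1, 24767492 in Heat 2, 16736267 in Heat 3, 28301155 in the library labelled meTKO 1 and 29530965 in meTKO 2. The libraries together covered 33637030 cytosine positions in 19614088 CpGs, and 873168 positions were covered in all 7. Input reads numbered 22520084 (wild-type J1), 10638950 (wild-type E14), 11273300 (Dnmt3a-KO), 25274172 (Dnmt3b-KO), 20788820 (Dnmt3a and Dnmt3b double KO), 8560355 (triple KO), 9486743 (Dnmt1-null), 54861903 (Np95-null; Np95 is the cofactor that recruits Dnmt1) and 79873148 (fibroblasts).

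The first comparison asked how many cytosines each protocol left unconverted in DNA without methylation. Alkaline libraries read 5.62% ± 2.10 of calls as methylated (SD, n = 2) and Heat libraries 1.40% ± 1.86 (SD, n = 3). Part of the excess in the Alkaline libraries sat in a few high-copy blocks on chromosomes 2 and 9. In the nuclear tiles without an input row, which hold these blocks, the level was 25.2% in Alkaline (20.2 and 30.1%) and 1.40% ± 1.86 (SD, n = 3) in Heat, while in the tiles with an input row it was 3.34% (2.49 and 4.19%) and 1.40% ± 1.86. Heat 2 lay apart from the other Heat libraries, with 3.54% against 0.333% in Heat 1 and 0.312% in Heat 3, and in tiles with an input row it lay between Alkaline 2 (2.49%) and Alkaline 3 (4.19%).

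The overall difference of −4.22 percentage points had an exact permutation p of 0.2, the smallest that 3 against 2 libraries allow, with no overlap between groups. In tiles with an input row the difference was −1.95 and the groups overlapped (exact permutation p = 0.4). Without Heat 2 the differences were −5.30 points overall and −3.02 in tiles with an input row, where the groups no longer overlapped, and without Alkaline 3 they shrank to −2.74 and −1.09. Counting error, with calls taken as independent, was small beside these differences: the Wilson interval of Heat 1 ran from 0.330 to 0.336%.

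The block at the start of chromosome 9 (3000001 to 3039000) read 21.9% methylated in Alkaline 2 and 34.0% in Alkaline 3, against 0.361, 3.40 and 0.329% in Heat 1, 2 and 3. It took 4.46 and 4.21% of all calls of the Alkaline libraries and 3.16, 2.43 and 2.75% of those of Heat 1, 2 and 3. In the library labelled meTKO 1 and in meTKO 2 it took 0.947 and 1.09%. The block on chromosome 2 (98502001 to 98508000) read 21.2 and 29.9% in the Alkaline libraries and 0.329, 3.72 and 0.283% in the Heat libraries. A second block on chromosome 9 (35112001 to 35114000) read 17.1 and 25.9% against 0.318, 2.26 and 0.281%, and a block on chromosome 12 (3109001 to 3111000) 19.3 and 26.1% against 0.456, 7.49 and 0.356%. Not every such block was raised: on chromosome 11 (3027001 to 3100000) the Alkaline libraries read 2.36 and 3.76%, and on chromosome 17 (39980001 to 39986000) 1.57 and 4.55%. The blocks were chosen after their values were seen. By whole chromosome, chromosome 9 stood at 15.5% ± 4.74 and chromosome 2 at 12.8% ± 5.08 in Alkaline (SD, n = 2), the only chromosomes on which the protocols did not overlap; on every other chromosome the overlap came from Heat 2 alone. The X chromosome read 3.51% ± 1.17 in Alkaline and 1.51% ± 2.01 in Heat, the Y chromosome 3.56% ± 0.755 and 1.64% ± 2.20, mitochondrial DNA 2.42% ± 0.659 and 1.26% ± 1.72, and repeat-like tiles 3.03% ± 1.24 and 1.31% ± 1.76. None of the 26 chromosome and class tests reached an adjusted p under 0.433 by exact permutation, which this design rules out in any case.

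**Figure D1:**
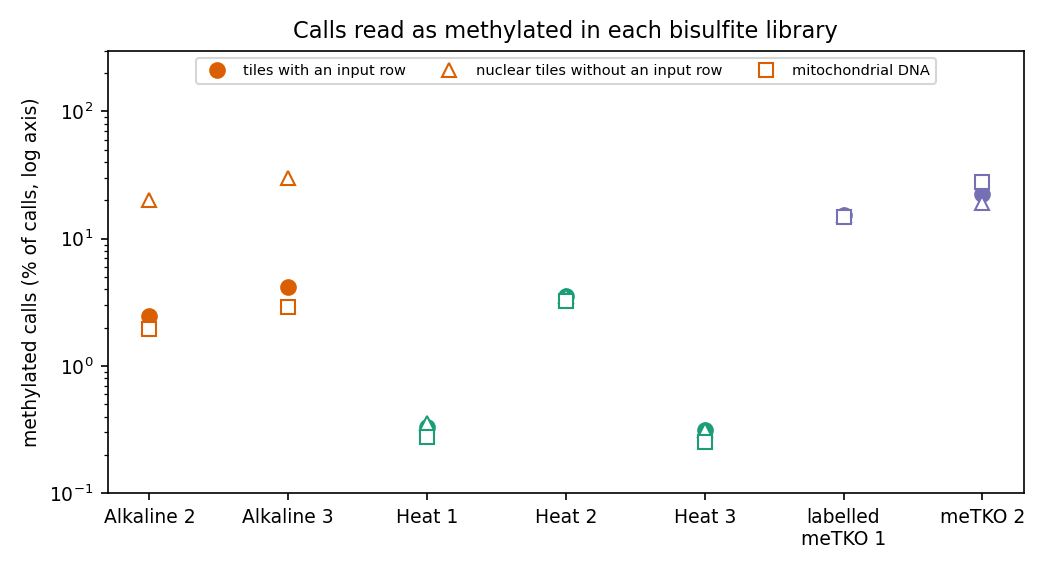
Percent of calls read as methylated (log axis) in each of the 7 bisulfite libraries, in tiles with an input row (filled circles), nuclear tiles without one (triangles) and mitochondrial DNA (squares); colours mark the groups. The triangles of Alkaline 2 (20.2%) and Alkaline 3 (30.1%) lie far above their circles, while in the Heat libraries the symbols lie close together.

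Along the genome, none of 24992 windows of 100 kb passed the edgeR test of level between Heat and Alkaline, with 13 windows at an unadjusted p under 0.05 and a median log2 change in odds of −2.12; no other tool was run on levels. Without Heat 2, 23633 windows were lower in Heat. These windows largely repeat 1 shift between whole libraries. For the level over all calls, 2 libraries against 2 gave an exact permutation p of 0.333. Levels by CpG density also overlapped in all 6 groups: from tiles with 1 to 5 CpGs to tiles with over 60, the level went from 2.97 to 1.45% in Alkaline 2, from 4.47 to 2.28% in Heat 2, from 4.50 to 4.65% in Alkaline 3, from 0.310 to 0.819% in Heat 1 and from 0.281 to 0.926% in Heat 3. No position was methylated in at least 50% of calls in each of the 5 libraries, out of 4231 positions with at least 10 calls in every library. A count of 0 allows a share of up to 0.0709% of such positions. They are not a sample of the genome, since chromosomes 17 (946), 9 (917), 8 (546) and 11 (525) and mitochondrial DNA (298) held most of them, and neighbouring positions share reads.

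The second comparison asked how much methylation M.CviPI had added at CpG cytosines. The calls hold no GpC sites outside CpGs, so the full extent of added methylation was not measured. In meTKO 2, 87.0% of calls at the inner cytosines of CGCG, which are GpC sites, were methylated (Wilson interval 86.9 to 87.1%), against 26.5% at the outer cytosines and 20.6% at lone CpGs. The library labelled meTKO 1 showed no such preference: 12.4% at inner cytosines, 11.9% at outer cytosines, and somewhat more at lone CpGs. In the 5 libraries without added methylation the inner cytosines read 2.06% ± 1.67 (SD, n = 5). The excess at GpC sites was thus seen in meTKO 2 alone, and every value of the meTKO group that follows includes the library labelled meTKO 1.

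Over all calls, the library labelled meTKO 1 read 15.3% and meTKO 2 22.3%, a mean of 18.8% ± 4.98 (SD, n = 2) against 3.09% ± 2.86 (SD, n = 5) in the unmethylated libraries. Both lay above all 5, with an exact permutation p of 0.0952, the smallest possible; at inner cytosines the means were 49.7% ± 52.7 and 2.06% ± 1.67 with the same p. The 2 libraries ran in opposite directions with CpG density: from tiles with 1 to 5 CpGs to tiles with over 60, meTKO 2 rose from 17.8 to 36.9% while the library labelled meTKO 1 fell from 19.4 to 8.94%. The share of CpGs that follow a guanine is unknown in each density group. The rise in meTKO 2 therefore cannot be read as a preference of the enzyme for CpG-dense DNA. On mitochondrial DNA they read 28.1 and 14.7%.

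**Figure D2:**
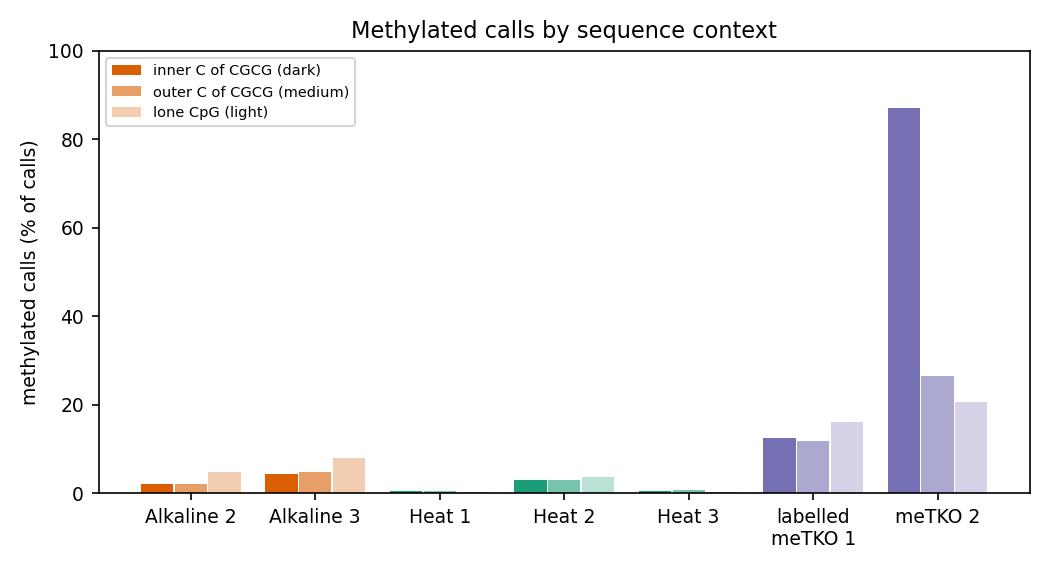
Percent of calls read as methylated at inner cytosines of CGCG (dark bars), outer cytosines of CGCG (medium bars) and lone CpGs (light bars) in each bisulfite library; 1 bar is 1 library and colours mark the groups. In meTKO 2 the inner cytosines reach 87.0%, while the first bars of the library labelled meTKO 1 are at 12.4 and 11.9%.

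By window, 23652 of 24992 windows passed edgeR's test of level, all higher in meTKO than in the mean of Heat and Alkaline. The median log2 change in odds was 3.81. With the replicate number as a block, 0 windows passed. Since 99.9% of all windows had no overlap between these groups, the 23652 windows largely repeat 1 shift between whole libraries. This count fell to 0 without the library labelled meTKO 1, meTKO 2, Alkaline 2, Alkaline 3, Heat 1 or Heat 3, and rose to 24989 without Heat 2. The 5 windows with the largest rise lay on chromosome 7 (8800001 to 8900000; log2 change 7.30, adjusted p = 0.0317), chromosome 4 (146200001 to 146300000; 5.76), chromosome 12 (61800001 to 61900000; 5.34) and the X chromosome (40700001 to 40800000, 5.33; 129100001 to 129200000, 5.28). Where calls were lost by leaving out a library, these 5 windows kept changes of 4.62 to 8.37, with adjusted p up to 0.236. In the window on chromosome 7 the library labelled meTKO 1 read 21.7% and meTKO 2 20.3%, against 0 to 0.877% in the other 5. These windows held few calls (111 to 210 per library on chromosome 7), and small baselines enlarge such log changes.

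The third comparison asked which parts of the genome each protocol over- or under-represents. CpG-rich DNA differed more between single libraries than between protocols. In tiles with over 60 CpGs per kb, log2 relative coverage was 0.48 in Alkaline 2 and −0.15 in Alkaline 3, and −0.63 in Heat 1, 0.41 in Heat 2 and −0.26 in Heat 3. The library labelled meTKO 1 reached 0.97 and meTKO 2 0.37. By replicate number, the libraries numbered 2 lay close together (0.37 to 0.48), as did Alkaline 3 and Heat 3. Heat 1 and the library labelled meTKO 1 lay far apart. Whether the numbers mark a shared preparation cannot be told from so few libraries, and the tests of density groups did not pair by them. The 8 ES cell inputs stood at −0.14 ± 0.04 (SD, n = 8) and the fibroblast input at −0.21.

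Heat and Alkaline overlapped in every density group. In the 5 groups up to 60 CpGs the differences lay between −0.23 and 0.03. With 1 library left out, the difference ran from −0.20 to −0.0028 in tiles with 21 to 40 CpGs. It ran from −0.43 to −0.052 in tiles with 41 to 60 CpGs. In the group with over 60 CpGs it was −0.33 (exact permutation p = 0.4, −0.64 to −0.014 with 1 library left out). The meTKO libraries were above Heat by 0.83 (exact permutation p = 0.4; 0.53 to 1.13 with 1 library left out) and above Alkaline by 0.50 (exact permutation p = 0.667; 0.19 to 0.81 with 1 library left out) in that group, with overlap. In tiles with 1 to 5, 11 to 20 and 21 to 40 CpGs both meTKO libraries lay outside the Heat and the Alkaline range, at −0.27 ± 0.04, 0.29 ± 0.04 and 0.47 ± 0.13 (SD, n = 2), which 2 libraries cannot bring past the threshold. In these groups meTKO 2 (−0.236, 0.261 and 0.382) lay close to Heat 2 (−0.205, 0.232 and 0.377). The library labelled meTKO 1 lay further out (−0.299, 0.314 and 0.560).

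Against the inputs, the meTKO libraries were lower in tiles with 1 to 5 CpGs (difference −0.23) and higher in every denser group, up to 0.80 over 60 CpGs (exact permutation p = 0.0444 and adjusted p = 0.0444 in all 6 groups, the smallest possible); the library labelled meTKO 1 is 1 of the 2. Leaving out any library of either group ends this call, since fewer libraries cannot reach it. Alkaline libraries were lower in tiles with 1 to 5 CpGs (difference −0.10) and higher by 0.12, 0.23 and 0.30 in tiles with 11 to 20, 21 to 40 and 41 to 60 CpGs (exact permutation p = 0.0444, adjusted p = 0.0667; the 0.30 ran from 0.13 to 0.46 with 1 library left out), and over 60 CpGs they overlapped the inputs. Heat libraries overlapped the inputs in all 6 groups, with adjusted exact permutation p from 0.2 to 0.824. This rested on single libraries: without Heat 1 the others differed from the inputs in tiles with 1 to 5, 6 to 10, 11 to 20 and 21 to 40 CpGs (−0.12, 0.010, 0.14 and 0.23), and without Heat 2 over 60 CpGs (−0.31), each with an exact permutation p of 0.0444, not adjusted. Restricting the denominator to positions covered in every bisulfite library reversed the Heat and Alkaline differences from the inputs in most groups, and that of meTKO in tiles with 6 to 10 CpGs (−0.012).

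**Figure D3:**
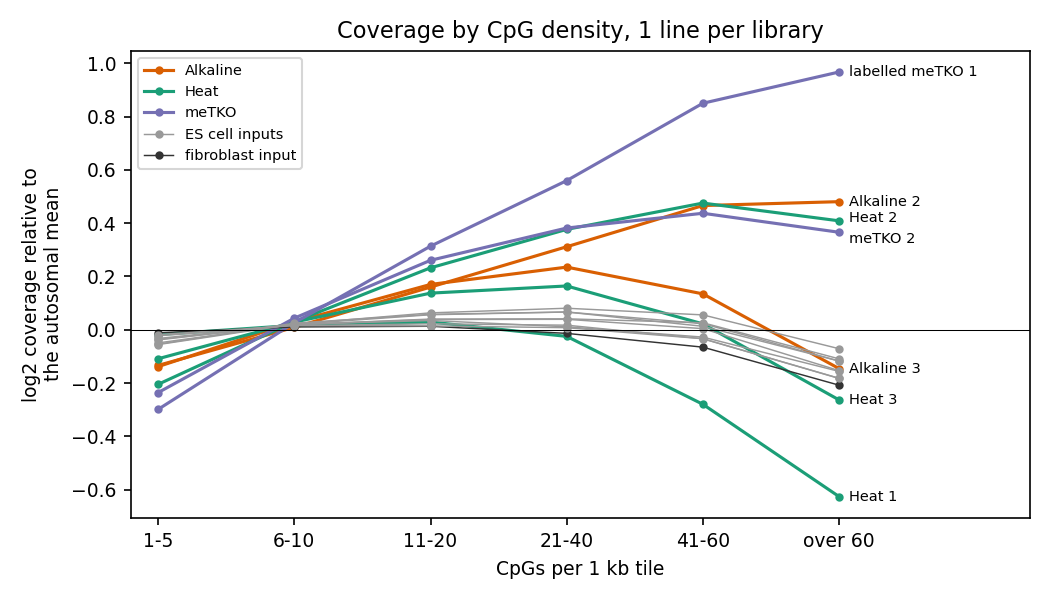
Log2 coverage relative to the autosomal mean (vertical axis) against CpGs per 1 kb tile (horizontal axis), 1 line per library, for the 7 bisulfite libraries (coloured by group), the 8 ES cell inputs (grey) and the fibroblast input (black). In tiles with over 60 CpGs the Heat libraries spread from −0.63 to 0.41 around the inputs, and the library labelled meTKO 1 is highest at 0.97.

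Of 25550 windows of 100 kb, 1 passed the edgeR test of coverage between Heat and Alkaline, on chromosome 6 (47600001 to 47700000; log2 change −0.58 ± 0.10 SE, adjusted p = 0.00485), and 770 had an unadjusted p under 0.05. Its input was 2.76 times the median, outside the rule for named windows, so it was chosen after its values were seen. Its coverage was 60.7 and 53.0 CPM (calls scaled to library size) in the Alkaline libraries and 35.3 to 42.5 in the Heat libraries. It was lost without Alkaline 2, without Heat 1 or without Heat 2, while 14 windows passed without Alkaline 3 and 2 without Heat 3.

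Between meTKO and Heat, 27 windows passed, 21 higher and 6 lower in meTKO. The higher ones were CpG-rich (median 999 CpGs, against 685 over all windows) and the lower ones CpG-poor (median 449). Over all 25550 windows the log2 change also rose with the number of CpGs (Spearman correlation 0.74). In 35.2% of all windows the 2 groups did not overlap. The windows that passed may therefore largely be the ends of this slope along the genome, and not local differences. The largest rises were on chromosome 4 (133000001 to 133100000, log2 change 0.59; 114500001 to 114600000, 0.57), chromosome 17 (66400001 to 66500000, 0.55), chromosome 2 (56900001 to 57000000, 0.51) and chromosome 1 (64700001 to 64800000, 0.50), and the largest falls on the Y chromosome (2300001 to 2400000, −1.30), chromosome 6 (79000001 to 79100000, −0.70), chromosome 18 (52300001 to 52400000, −0.67), chromosome 10 (128500001 to 128600000, −0.57) and chromosome 13 (77500001 to 77600000, −0.55, but −0.12 and no longer past the threshold without its 1 tile that has no input row). The count was set by single libraries: 3 windows without the library labelled meTKO 1, 368 without meTKO 2, 3 without Heat 1, 2710 without Heat 2, 201 without Alkaline 2 and 193 without Alkaline 3. DESeq2 found 598.

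Between meTKO and Alkaline, 10 windows passed, 1 higher and 9 lower in meTKO. Here too the log2 change rose with the number of CpGs over all windows (Spearman correlation 0.65). The groups did not overlap in 46.4% of all windows. The largest fall was the start of chromosome 9 (3000001 to 3100000; log2 change −2.12 ± 0.41 SE, adjusted p = 0.0249), where the high-copy block lies; without the tiles that have no input row its change was 0.0093. Among windows with an input of 0.5 to 2 times the median, the next were on the Y chromosome (2300001 to 2400000, −1.32), the X chromosome (104700001 to 104800000, −1.03), chromosome 17 (93100001 to 93200000, −0.74) and chromosome 13 (77500001 to 77600000, −0.65), the last of which turned to 0.17 without those tiles. The higher window lay on chromosome 3 (33900001 to 34000000, 0.48). The smallest adjusted p, 0.000285, belonged to the chromosome 6 window (47600001 to 47700000, −0.71) already described, which lies outside that input range and was chosen after its values were seen. The count was 50 without Alkaline 2, 54 without Heat 2, 29 without Heat 3 and 44 without meTKO 2, and 15, 14 and 8 without Heat 1, Alkaline 3 and the library labelled meTKO 1.

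Repeat-like tiles and mitochondrial DNA were far above the autosomal mean in every library. Repeat-like tiles stood at 2.86 ± 0.09 in Heat (log2, SD, n = 3), 2.81 ± 0.07 in Alkaline, 2.78 ± 0.02 in meTKO (both n = 2) and 4.38 ± 0.23 in the ES cell inputs (n = 8), by which they were defined. Every bisulfite library was below every input there (difference −1.53 for Heat, exact permutation p = 0.0121, adjusted p = 0.267). Since these tiles were chosen for high reads in the same inputs, this direction was favoured in advance. The difference and its p therefore cannot show a loss of repeats in the bisulfite libraries. Mitochondrial DNA stood at 8.50 ± 0.26 in Heat, 8.43 ± 0.14 in Alkaline and 7.79 ± 0.18 in meTKO; it was not tested against the inputs, whose mitochondrial rows cover other tiles. The X chromosome stood at −0.74 ± 0.09 in Heat, −0.74 ± 0.03 in Alkaline, −0.89 ± 0.03 in meTKO and −0.84 ± 0.03 in the inputs, and the Y chromosome at −0.43 ± 0.14, −0.43 ± 0.004, −0.65 ± 0.04 and 0.73 ± 0.51. Group means of the autosomes ranged from −0.15 to 0.31 in the bisulfite libraries. No chromosome or class passed after adjustment in any of the 6 comparisons by exact permutation.

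Coverage over 100 kb windows varied by 23.7% ± 2.73 (coefficient of variation, SD, n = 3) in Heat, 24.8% ± 0.0974 in Alkaline, 29.5% ± 3.60 in meTKO (both n = 2) and 28.4% ± 3.22 in the inputs (n = 8). The differences of Heat (exact permutation p = 0.0485, adjusted p = 0.145) and Alkaline (exact permutation p = 0.0444, adjusted p = 0.145) from the inputs did not pass after adjustment, and both turned positive without repeat-like tiles. None of the other 4 comparisons passed.

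The inputs, 1 library per line, differed in relative reads on some chromosomes, which need not be a difference in copy number. On the Y chromosome the ES cell inputs averaged 0.73, while Heat, Alkaline and meTKO averaged −0.43, −0.43 and −0.65, so that value depends on the kind of library. In the Dnmt3a-KO input, chromosome 8 stood at 0.44 and chromosome 11 at 0.49 (log2 relative reads), against medians of 0.05 and 0.10 over the 9 inputs. In the Np95-null input chromosome 11 stood at 0.45. In the Dnmt1-null input the Y chromosome was at −0.53 against a median of 0.89, repeat-like tiles were at 3.84 against 4.43, and mitochondrial DNA was at 7.68 against 5.45. The triple-KO input had mitochondrial DNA at 6.88 and the wild-type J1 input at 5.01. In the fibroblast input the X chromosome was at −0.41 against −0.83, the Y chromosome at 0.20, repeat-like tiles at 3.98 and mitochondrial DNA at 4.43. The mitochondrial values rest only on tiles without bisulfite calls, since the 15 mitochondrial tiles with such calls have no input row. They are therefore a weak measure of the mitochondrial DNA of a line. With 1 library per line all values of the inputs here are without a test.

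**Figure D4:**
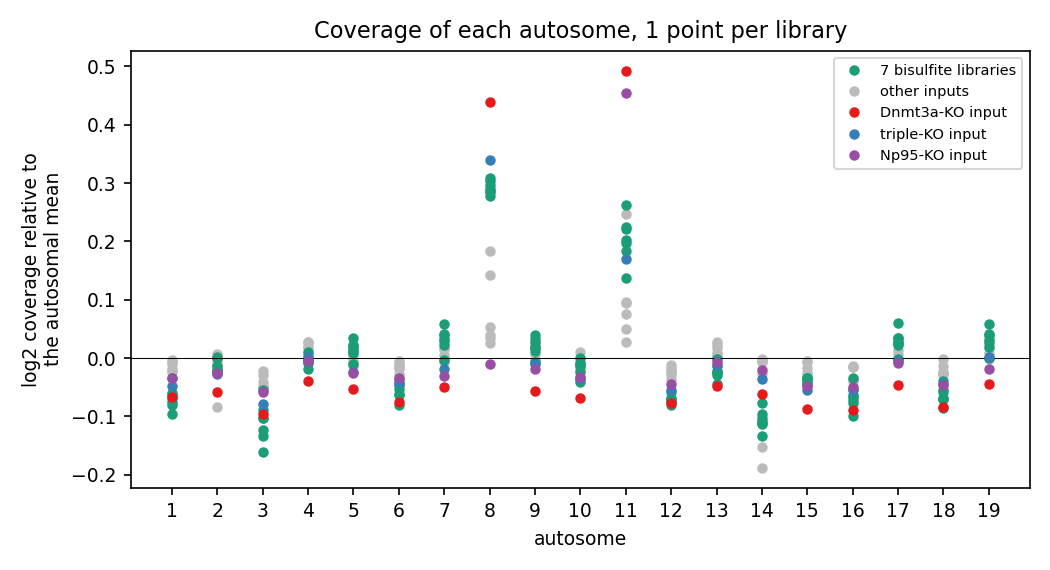
Log2 coverage relative to the autosomal mean (vertical axis) for each autosome (horizontal axis), 1 point per library, for the 7 bisulfite libraries of TKO cells (green), 3 single inputs (red, blue and purple) and the other 6 inputs (grey). The Dnmt3a-KO input is high on chromosomes 8 (0.44) and 11 (0.49) and the Np95-null input on chromosome 11 (0.45).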

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

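Among 30 values of the 8 ES cell inputs (chromosomes, classes, density groups and evenness), 3 had a single library far from the others by Dixon's criterion, which compares the gap to the nearest library with the range. Chance alone gives such a gap in about 1 group in 20, so these are values to look at again, and no explanation was tested. The Dnmt1-null input had log2 relative reads of −0.53 on the Y chromosome, where the other 7 lay between 0.84 and 0.95. The same input stood at 3.84 in repeat-like tiles, where the others lay between 4.36 and 4.58. The Dnmt3a-KO input stood at −0.083 on chromosome 18, close to the threshold; its chromosomes 8 and 11, at 0.44 and 0.49, raise the mean to which all its chromosomes are compared.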

How the results depend on the processing

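Of 1278 recomputed values for 126 results, 902 kept their direction and side of the threshold or, for counts of windows, a similar size. Another 276 missed a threshold passed before (many because fewer libraries cannot reach it), 10 passed one newly, 31 moved and 59 reversed. Permutation tests among bisulfite libraries cannot reach the threshold in any setting, so their side was fixed in advance. The levels per library (Heat minus Alkaline, meTKO minus the rest) kept their direction in every alternative run, with too few libraries to reach the threshold in any, and the persistent sites stayed at 0. Unless a construction is named, the cause was not tested. With positions covered in every bisulfite library, a selection by coverage itself, log2 differences reversed: Heat minus Alkaline to −0.018, −0.0016, 0.013 and 0.00050 (1 to 5, 6 to 10, 11 to 20, 21 to 40 CpGs); meTKO minus Heat and minus Alkaline to −0.034 and −0.036 (6 to 10); Heat minus inputs to 0.11, −0.055, −0.11 and −0.12 (1 to 5, 11 to 20, 21 to 40, 41 to 60); Alkaline minus inputs to 0.13, 0.023, −0.068, −0.11, −0.097 and −0.033 (all 6 groups); meTKO minus inputs to −0.012 (6 to 10); chromosome 8 against inputs to −0.049 (Heat), −0.059 (Alkaline) and −0.0043 (meTKO); X to −0.019 (Heat minus Alkaline), −0.19 and −0.17 (Heat and Alkaline minus inputs); Y to 0.075 (Heat minus Alkaline); repeat-like tiles to 0.21 and 0.30 (meTKO minus Heat and minus Alkaline). Medians over tiles gave −0.0081 (meTKO minus Heat, 6 to 10), 0.028 (Alkaline minus inputs, 6 to 10) and 0.049 (Heat minus inputs, over 60), and adding the fibroblast input 0.00095 (Alkaline, 6 to 10). Tiles with an input of 0.5 to 2 times the median, which drop much of the X chromosome of male lines, gave −0.11 for X (Heat) and −0.11 (Alkaline) minus inputs. Evenness minus inputs became 0.686 (Heat), 2.11 (Alkaline) and 7.50 (meTKO) points without repeat-like tiles, −3.68 (Heat) and −2.56 (Alkaline) with the fibroblast input, and −5.52 (meTKO) in 1 Mb windows. Counts of windows became 598 (meTKO against Heat) with DESeq2; 0, 9, 1 and 52186 (coverage of Heat against Alkaline, meTKO against Heat, meTKO against Alkaline, meTKO level) in 20 kb windows, of which more were tested with fewer calls each; 12130 of 12163 (meTKO level) with 500 calls per window; and 0 (meTKO level) with the replicate number as a block. Without the tiles that have no input row, the chromosome 9 window became 0.0093 and that on chromosome 13 0.17 (meTKO against Alkaline).

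Leaving out each library in turn, a group cut to 1 library taking the spread of the others, gave ranges of −0.021 to 0.073, −0.0047 to 0.016 and −0.082 to 0.020 (Heat minus Alkaline; 1 to 5, 6 to 10, 11 to 20 CpGs), −0.13 to 0.25 and −0.31 to 0.21 (Heat minus inputs; 41 to 60, over 60), −0.010 to 0.010 and −0.0096 to 0.62 (Alkaline minus inputs; 6 to 10, over 60), 0.50 to 1.10 (meTKO minus inputs, over 60); for Heat minus Alkaline −0.0014 to 0.012 (chromosome 8), −0.036 to 0.049 (X), −0.069 to 0.072 (Y), −0.022 to 0.22 (mitochondrial) and −0.0075 to 0.096 (repeat-like); −0.080 to 0.023 (meTKO minus Alkaline, repeat-like); evenness −2.48 to 0.246 (Heat minus Alkaline), −6.07 to −3.34, −3.97 to −2.81 and −1.38 to 3.72 (Heat, Alkaline, meTKO minus inputs); and windows 0 to 14, 3 to 2710 and 8 to 54 (the coverage comparisons in the order above), 0 to 23633 (Heat against Alkaline level) and 0 to 24989 (meTKO level). Among these ranges, only the counts of windows used a spread taken from the other libraries. The ranges of coverage and evenness are plain differences in means. With 1 call at the median position, depth limits single CpGs, not the pooled levels. Tests around gene starts were not run, and mitochondrial DNA gave no value for tiles with inputs in range.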

Other observations

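The tests of explanations below, and the comparisons of strands and single libraries, were chosen only after the values had been seen. On mitochondrial DNA the 2 strands were covered very unequally. The ratio of forward to reverse calls was 0.0659 and 0.0654 in the Alkaline libraries, 0.0656, 0.0804 and 0.0540 in Heat 1, 2 and 3, 0.143 in the library labelled meTKO 1 and slightly lower in meTKO 2. The thinly covered forward strand was also the less converted one: 15.1 and 16.8% of its calls read as methylated in the Alkaline libraries and 15.5% in Heat 2, against 1.08, 2.02 and 2.25% on the reverse strand. In Heat 1 and Heat 3 the strands read 0.408 and 0.257% and 0.268 and 0.245%, and the intervals overlapped in both. Over the rest of the nuclear genome the strands had equal shares (forward over reverse 1.00 in Alkaline 2).

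High-copy nuclear DNA also read differently on its strands. In the block at the start of chromosome 9 the forward strand, with fewer calls, read 47.2 and 49.9% in the Alkaline libraries, an interval of 19.7 to 20.3% in Heat 2 and 43.0% in the library labelled meTKO 1, and the reverse strand 9.33, 19.6, 1.22 and 6.34%. In the block on chromosome 2 it was the reverse strand that had fewer calls and read higher, for example 10.4% against 1.63% in Heat 2. No explanation of this was tested, and the base composition of the strands was not analysed here. In meTKO 2 the order was the opposite (0.656% forward and 29.2% reverse on chromosome 9).

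Chromosome 8 stood at 0.34 on the log2 scale in the triple-KO input and between 0.28 and 0.31 in all 7 bisulfite libraries of TKO cells, but it was also raised in the Dnmt3a-KO (0.44), wild-type J1 (0.18) and double-KO inputs (0.14). Chromosome 11 stood between 0.14 and 0.26 in the bisulfite libraries and at 0.17 in the triple-KO input. Chromosome 14 was lower in the Dnmt3b-KO (−0.19) and the double-KO input (−0.15) than in the wild-type J1 input (−0.0065).

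The library labelled meTKO 1 read 15.3% of calls as methylated without a GpC preference. Methylation by M.CviPI would need inner CGCG cytosines far above outer ones, and the difference was 0.542 percentage points. Admixed DNA with CpG methylation would leave mitochondrial DNA low, and it read 14.7%; a swap with an unmethylated library would need a GpC preference there, and the highest difference among those 5 was 0.0144 points. Incomplete conversion of unmethylated DNA is a candidate explanation: it predicts more unconverted calls on the mitochondrial forward strand, where the ratio to the reverse strand was 4.93. A single wrong label, or an M.CviPI reaction that did not work, stays open, and the biological explanation that the design names, added methylation, is the one that the first value argues against.

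The Alkaline libraries read more unconverted calls in nuclear tiles without an input row, at 8.13 and 7.19 times the level of the other tiles. On the strand with more calls in the chromosome 2 and 9 blocks, the Alkaline libraries read 3.36 to 5.07 times the level of other nuclear tiles, which depth or generally poorer conversion would give elsewhere too, but the highest ratio was 0.868 in the Heat libraries and 0.492 in Heat 2 and the library labelled meTKO 1. On the strand with fewer calls both stay open: the ratio reached 1.98 in Heat 1 and Heat 3 and was at least 2.08 in Heat 2 and the library labelled meTKO 1, against 9.21 to 17.1 in the Alkaline libraries, and Heat 2 and the library labelled meTKO 1 also read high in small blocks on chromosome 12 (7.49 and 24.1%) and chromosome 6 (103599001 to 103600000; 7.94 and 33.4%, Alkaline 13.0 and 14.7%). Methylation left in the cells would show in Heat libraries of the same cells, and Heat 1 and Heat 3 read at most 0.353% in tiles without an input row. Alkaline denaturation itself and the kit, which the labels do not assign, remain open, with 2 libraries.

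Heat 2 read 3.54% over all calls and lay between the other Heat libraries and the Alkaline libraries. In tiles with an input row it lay between Alkaline 2 (2.49%) and Alkaline 3 (4.19%). On mitochondrial DNA it read above both of them (3.25% against 1.96 and 2.89%). An Alkaline library under a Heat label might be expected to read above the other nuclear tiles on the strand with more calls in the chromosome 2 and 9 blocks. The higher of the ratios of Heat 2 was 0.436. This cannot decide the label, since the kit and not the denaturation may have raised those blocks in the Alkaline libraries. If Heat 2 held DNA with CpG methylation from other cells, its mitochondrial DNA would be near the 0.275% of Heat 1, and it read 3.25%. A wrong label, a different kit or a different conversion run stays open, and no biological explanation was tested.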
